A study of Saccharomyces cerevisiae with 3 samples.

How the data were processed

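Each of the 3 samples was a two-colour array of budding yeast RNA. Per the labels, the Cy3 channel of every array held RNA from mRNP, the messenger ribonucleoprotein fraction, and the Cy5 channel held RNA from a fraction called Poly, read here as polysomes, the mRNAs carrying several ribosomes. A value on such an array compares the 2 fractions of 1 sample rather than 2 samples. The array titles are G0, Y5 and Y10, each followed by mRNP vs. Poly. The labels do not explain these letters or give a unit for the numbers, so G0, Y5 and Y10 are used as names. With 1 array per group there were no replicates and no dye swap.

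The deposited table gave 1 log ratio per spot and array for 8832 spots. The base of the logarithm, the centring and the direction of the ratio are not given in the sources used here. The deposited values were taken as log2. Base 10 was set aside because the value farthest from 0 on the Y5 array would then mean a 2.65e+07-fold ratio, and a natural logarithm was not excluded by the values. The medians of the deposited columns were 0.0735 on G0, 0.067 on Y5 and 0.071 on Y10. The direction was taken as likely Cy5 over Cy3, polysome over mRNP. The basis was the usual red-over-green convention and the value of GCN4, an mRNA held back from translation in well-fed cells, which lay at percentile 5.82 on G0. The list of mRNAs with reported upstream open reading frames did not decide the direction (percentile 38.5 on G0). The rule fixed before the data were examined gave no direction unless GCN4 and this list pointed the same way. Taking a direction departed from that rule. The array titles name mRNP before Poly, which could be read as the opposite direction and does not settle it. Should the direction be the opposite, every sign below turns. Per the labels, the design involved a regression correlation, with no further detail on scanner, background or spot filter. No channel intensities were used here, so neither depth nor signal over background is known, and the number of arrays limits the precision.

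Gene names came from the platform annotation, which gave 1 gene symbol for 6623 spots, several for 0 and none for 2209. All 5574 genes matched the RefSeq gene table of assembly R64 through their gene identifiers, and current symbols were taken from it. No coordinates are given, since no build is named for the array. Of the genes, 4605 had 1 spot, 890 had 2 and 79 had 3 or 4. The gene lengths are written as coding length because 96.8% of them are multiples of 3. Whether they include introns was not checked, so for genes with introns they may exceed the coding sequence.

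The Y10 array did not share its row numbers with the others. Its last value stood in row 8064 of 8832, and by deposited row number it was unrelated to G0 (r = 0.037 across spots) and to Y5 (r = 0.016). The correlation between the 2 spots of a gene was 0.576 on G0 (882 genes) and 0.643 on Y5 (886 genes), but 0.0337 on Y10 (702 genes). The row numbers of Y10 were found, after the data were seen, to follow 32 sectors of 252 spots rather than 32 sectors of 276. Renumbered in this way, the first 192 spots of each sector correlated with Y5 (median r = 0.521 over 16 rows of 12 spots) and repeat spots within Y10 correlated at r = 0.309 (453 genes). All Y10 values below use these 6008 spots (4446 genes). The last 60 spots of each sector, 1814 with a value, were left out because their place was less sure. Every Y10 result therefore rests on a numbering inferred from the data.

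Each array was centred on its own median and the spots of a gene were averaged. Differences between arrays were taken per gene. No test or p-value across arrays was possible, and the fixed rule of size was 1 log2 unit. Because every ratio is relative to the median of its array, a change of all mRNAs together cannot be seen. Genes with 2 spots gave the technical error of the difference for 1 spot, an SD of 0.448 for Y5 minus G0, 0.631 for Y10 minus G0 and 0.558 for Y10 minus Y5. This error holds neither the spread between cultures nor that between hybridisations. Errors alone passed 1 log2 unit in 3.64%, 9.13% and 6.40% of genes with 2 spots for these differences, against 16.0%, 20.6% and 9.59% of genes with 1 spot. In the same order, the differences of the 2 spots of a gene correlated with r = 0.543, 0.268 and 0.197.

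Before the data were examined, 21 gene lists were fixed. Of these 20 had at least 5 measured genes, and the list of mitochondrially encoded transcripts had 0. The list written below as chaperones or cytosolic chaperones is that of cytosolic chaperones and heat shock. It also holds heat shock genes such as HSP12, HSP30 and HSP60, so not every member is a cytosolic chaperone. A list is described by its median, by an order-statistic 95% interval of the median over its genes, and by the percentile of the median among 10000 random lists of the same size. A list is said to stand apart below percentile 2.5 or above percentile 97.5. These describe genes on these arrays, and genes are not replicates. Lists could not be matched on expression level without intensities, so matching on the G0 value in 10 bins was an alternative.

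Named genes followed a rule fixed before the data were examined, over genes measured on all 3 arrays: the 5 highest and 5 lowest on G0; the 10 highest and 10 lowest by the smaller of the 2 differences from G0; the 5 highest and 5 lowest for Y10 minus Y5; the 2 highest and 2 lowest members of each list; and GCN4, HAC1, ICY2, KAR2, CPA1, HAP4, FBP1, PCK1, GUT1, GUT2, TDH3, ENO2 and ACT1. ICY2 was not analysed here. Near-identical members of the ribosomal protein, glycolytic and elongation factor families can hybridise to each other's spots, so values of single members are uncertain.

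Alternative settings fixed before the data were examined were no centring, scaling to one median absolute deviation, quantile normalization, genes on all 3 arrays and the median of a gene's spots. Also fixed before were leaving out the outer 0.5% at each end, thresholds of 1.5-fold and 3-fold, matching on G0 and a trimmed mean (10% from each end). Further ones were pairs named with a final A or B averaged to 1 value, and coding length without ribosomal proteins. Near-identical genes named otherwise stayed separate. Those chosen after seeing the data were Y10 by deposited row number, Y10 with the last 60 spots of each sector added, centring each sector, genes with 2 or more spots only, and lists drawn from the 20 genes outside the list nearest in G0 value to each member. For Y5 minus G0, the lists drawn in this way for glycolysis had a typical G0 median of 1.97, against 2.0 for glycolysis itself. The procedure was tested on simulated data for Y5 minus G0 (5546 genes, 100 genes changed at each size). It placed 44% of changes of 1 log2 unit and 98% of changes of 2 log2 units past the threshold, with 5.03% of unchanged genes past it. The simulated error was that of repeat spots, without a spread between hybridisations. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.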

Results

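The study followed yeast moved quickly from a carbon source it can ferment to one it cannot. For each of 3 samples, named G0, Y5 and Y10, 1 array compared RNA of the polysome fraction with RNA of the mRNP fraction. Higher values are read as more of an mRNA in the polysome fraction. This direction was assumed, against the rule fixed before, and is not given with the values. Values are log2 units relative to the median of each array, with the base of the logarithm assumed. A value was present for 8700 spots on G0, 8734 on Y5 and 7822 on Y10, and 5548, 5563 and 4446 genes were used. The SD across spots was 0.824 on G0, 0.802 on Y5 and 0.657 on Y10 as deposited. Across spots, G0 and Y5 correlated with r = 0.389, and with Y10 renumbered the correlations were 0.211 for G0 and Y10 and 0.463 for Y5 and Y10. There was no replicate array for any of the comparisons below, so no difference could be set against a spread between replicates.

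On the G0 array the highest group was glycolysis and fermentation. All 21 genes lay above the array median, with a list median of 2.0 (95% interval over genes 1.74 to 2.09), including CDC19, pyruvate kinase, at 2.46 and ENO2, an enolase, at 2.59. The tricarboxylic acid cycle (median 1.29, 15 genes), aminoacyl-tRNA synthetases (1.18, 21 genes), amino acid biosynthesis (1.08, 65 genes), sulfur amino acid metabolism (1.07, 30 genes), cytosolic chaperones (0.94, 31 genes), translation factors (0.85, 38 genes), cell wall and secreted proteins (0.81, 36 genes) and ergosterol and fatty acid synthesis (0.72, 30 genes) also had medians above all 10000 random lists. The proteasome (0.55, 36 genes) and the stress, trehalose and glycogen list (0.39, 37 genes) stood above most of them, at percentiles 99.99 and 99.7. Lists below the random lists were mitochondrial ribosomal proteins (−0.25, 77 genes, percentile 0.085) and gluconeogenesis, glyoxylate cycle and glycerol use (−0.33, 25 genes, percentile 1.24).

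Cytosolic ribosomal proteins (−0.08, 131 genes), ribosome biogenesis (0.01, 108 genes), the nuclear-encoded respiratory chain (0.01, 36 genes), hexose transport (−0.13, 24 genes), the unfolded protein response (0.19, 28 genes), histones (−0.39, 10 genes) and the mRNAs with reported upstream open reading frames (−0.06, 12 genes) did not stand apart on G0. Among genes measured on all 3 arrays, the highest on G0 were PUS9, a pseudouridine synthase, at 5.30, COQ1, of coenzyme Q synthesis, at 4.13, TGL2, a lipase, at 2.78, MET10, a sulfite reductase subunit, at 2.55 and CDC19. The lowest were BOR1, a borate transporter, at −3.23, RPL41A at −2.61, GLE1, of mRNA export, at −2.48, RPS30B at −2.40 and HMRA2 at −2.33. GCN4, the activator of amino acid synthesis genes, lay at −0.93. Of these, RPL41A had 2 spots and the others 1.

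**Figure D1:**
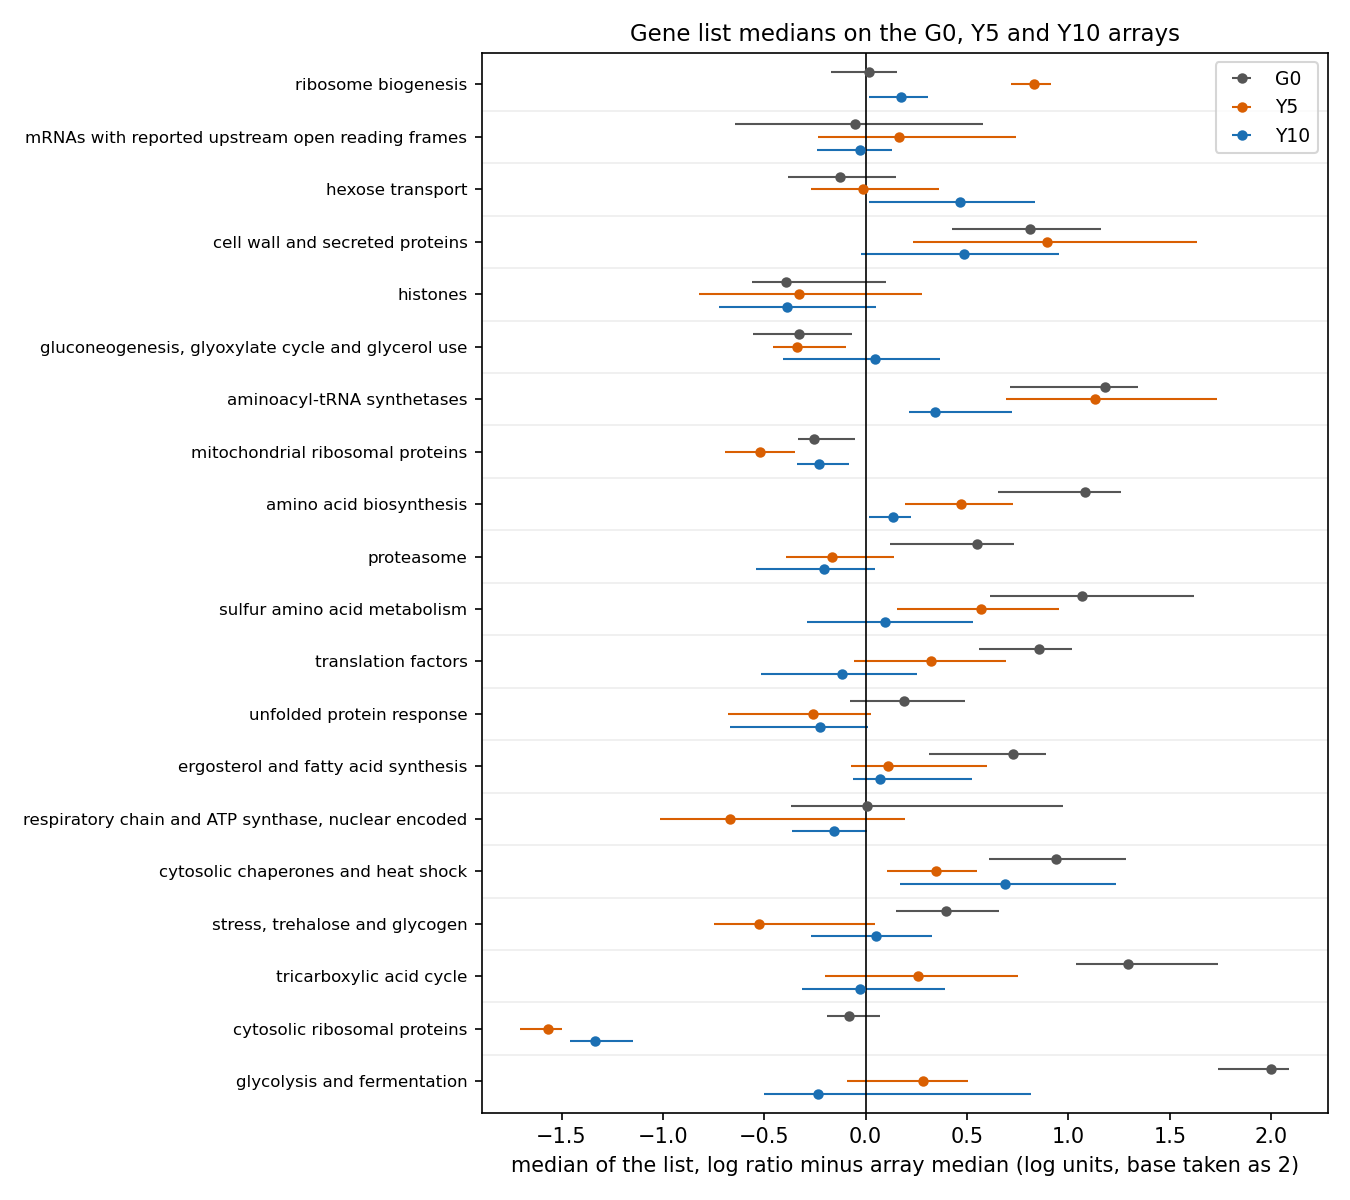
Median of each of 20 gene lists on the G0, Y5 and Y10 arrays (x axis, log ratio minus the array median, base taken as 2), with bars for the order-statistic 95% interval of the median over the genes of a list, not over arrays. Cytosolic ribosomal proteins lie at −0.08 on G0 and at −1.57 and −1.34 on Y5 and Y10, and glycolysis and fermentation at 2.0 on G0 and at 0.28 and −0.24 on Y5 and Y10.

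Between G0 and Y5, mRNAs of cytosolic ribosomal proteins were lower on Y5. Their list median differed by −1.50 (95% interval over genes −1.67 to −1.32), with 125 of 131 genes below 0 and 94 lower by at least 1 log2 unit. RPL1A differed by −3.45 (2 spots, −3.59 and −3.31) and RPL7A by −2.75, and RPL41A (0.61) and RPL22B (0.60) were among the 6 members above 0. mRNAs of ribosome biogenesis factors, which assemble ribosomes in the nucleolus, were higher on Y5, with a median of 0.75 (0.60 to 0.95), 97 of 108 genes above 0 and 38 by at least 1. Over both later arrays UTP6 (2.20 on Y5) and NOG2 (2.15) had the highest mean differences in this list, and NOP1 (−0.53) and TSR1 (−0.03) the lowest. The first list lay below and the second above all 10000 random lists.

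Glycolytic and fermentative mRNAs were also lower on Y5 than on G0, with a list median of −1.62 (−2.33 to −0.85) and 19 of 21 genes below 0. PDC5, a pyruvate decarboxylase, differed by −2.70 (2 spots), GLK1, glucokinase, by −2.83, CDC19 by −2.33, ENO2 by −2.05 and TDH3, glyceraldehyde-3-phosphate dehydrogenase, by −1.46. PFK1 and PFK2, the subunits of phosphofructokinase, were the 2 members above 0, both at 0.42. The tricarboxylic acid cycle list had a median of −1.04 (14 of 15 genes below 0), with IDH2, an isocitrate dehydrogenase subunit, at −2.37 and KGD2 at −1.37, while CIT1, citrate synthase, stood at −0.51 and CIT3 at 0.07. The nuclear-encoded respiratory chain and ATP synthase list had a median of −0.60 (30 of 36 below 0). Its members ranged from ATP16 at −2.20 and QCR2 at −1.56 to QCR10 at 1.68 and QCR6 at 2.32, and without the outer 0.5% of values QCR10 turned to −0.17. HAP4, the activator of respiratory genes, stood 1.11 higher. Gluconeogenesis, glyoxylate cycle and glycerol use did not stand apart (median −0.01, 25 genes). FBP1, of gluconeogenesis, differed by 0.37, PCK1 by 0.53, ACS1 by 0.96, MDH2 by 0.41, GUT1 by −0.46, GUT2 by −0.51, ADH2 by −0.90 and ALD4 by −2.04.

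Stress, trehalose and glycogen genes had a Y5 minus G0 median of −0.73 (28 of 37 below 0), with GRE3 at −2.57, HSP12 at −2.52, GDB1 at 0.57 and GAC1, a regulator of glycogen synthesis, at 1.34. Cytosolic chaperones had a median of −0.68 (21 of 31 below 0), the unfolded protein response −0.53 (24 of 28 below 0) and mitochondrial ribosomal proteins −0.30 (56 of 77 below 0). HAC1, the transcription factor of the unfolded protein response, differed by −1.92, the endoplasmic reticulum chaperone KAR2 by −1.31 and PDI1 by −1.24, against 1.09 for SIL1. HSP30 was 1.89 higher and SSB2 differed by −1.54. Translation factors (−0.51, 38 genes), ergosterol and fatty acid synthesis (−0.53, 30 genes), sulfur amino acid metabolism (−0.42, 30 genes), the proteasome (−0.40, 36 genes) and amino acid biosynthesis (−0.38, 65 genes) also lay below percentile 2.5. Aminoacyl-tRNA synthetases (−0.01, 21 genes), hexose transport (0.18, 24 genes), cell wall and secreted proteins (0.18, 36 genes), histones (0.06, 10 genes) and mRNAs with reported upstream open reading frames (0.30, 12 genes) did not. The cell wall list did stand apart with scaling to one spread (0.34), quantile normalization (0.36) or sector centring (0.34), whereas translation factors (−0.09) and ergosterol synthesis (−0.02) no longer did after quantile normalization, nor did these 2 (−0.25 and −0.12) and sulfur amino acid metabolism (−0.34) over genes on all 3 arrays. GCN4 was 2.26 higher and CPA1 differed by −0.68. ACT1, actin, differed by −1.24.

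Over all 5546 genes, 223 were at least 1 log2 unit higher and 583 at least 1 lower on Y5 than on G0, and after quantile normalization 229 and 346. Compared with random lists matched on the G0 value, the medians of translation factors, the tricarboxylic acid cycle, cytosolic chaperones, amino acid biosynthesis, sulfur amino acid metabolism, the proteasome and ergosterol synthesis no longer stood apart, whereas aminoacyl-tRNA synthetases (percentile 99.95) and cell wall proteins (above all matched lists) did so on the high side. Among genes with 2 or more spots the ribosomal protein median was −0.69 (13 genes), the medians of mitochondrial ribosomal proteins (−0.11, 10 genes) and stress genes (−0.27, 6 genes) no longer stood apart, and those of translation factors (0.34, 8 genes), amino acid biosynthesis (0.22, 7 genes) and ergosterol synthesis (0.40, 7 genes) turned positive.

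Between G0 and Y10, cytosolic ribosomal proteins and glycolysis were again lower on the later array. The ribosomal protein median was −1.29 (−1.64 to −1.01), with 90 of 108 genes below 0 and 65 by at least 1. RPL7A differed by −3.89 and RPL1A by −3.31, against 2.04 for RPL41A and 1.59 for RPL22B. Glycolysis and fermentation had a median of −1.57 (14 of 15 genes below 0), with CDC19 at −2.97, PDC5 at −2.77, GLK1 at −2.70, TDH3 at −2.14, PFK1 at −0.61 and PFK2 at −0.25. The tricarboxylic acid cycle median was −1.47, with all 11 genes below 0, among them KGD2 at −2.0 and IDH2 at −1.92, and CIT1 at −0.05. Ribosome biogenesis, at 0.14 (50 of 81 genes above 0), lay at percentile 97.1, short of standing apart, but did stand apart with scaling to one spread (0.28), quantile normalization (0.31), sector centring (0.22) or the last 60 spots added (0.16). UTP6 stood at 1.71 and NOG2 at 1.28, with TSR1 at −1.44 and NOP1 at −0.93.

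Lower medians on Y10 than on G0 were also found for sulfur amino acid metabolism (−1.14, 21 genes; MET22 −2.03, MET10 −1.93, MET31 1.11, MET4 0.81), amino acid biosynthesis (−0.85, 53 genes), aminoacyl-tRNA synthetases (−0.75, 19 genes) and translation factors (−0.75, 29 genes). Synthetases no longer stood apart with scaling to one spread (−0.34) or quantile normalization (−0.37). In amino acid biosynthesis, HOM2 differed by −2.70 and LYS9 by −2.50, and GLN1, glutamine synthetase, was 2.14 and TRP1 1.47 higher. GUS1 differed by −2.21 and HTS1 by −1.36, and GLN4 was 1.06 higher and CRS1 0.06. TEF1, elongation factor 1 alpha, differed by −2.87 (1 of its 2 spots on Y10, and −0.47 for Y10 minus G0 with the last 60 spots added) and HYP2 by −2.45, and RPG1 stood at 0.73 and TIF4631 at 0.06. Of the remaining lists, the nuclear-encoded respiratory chain (−0.58, 30 genes; ATP16 −2.77, QCR2 −1.93, QCR6 1.75, QCR10 0.39), the proteasome (−0.55, 32 genes; PRE9 −1.89, PUP3 −1.32, PRE8 0.31, PRE2 0.14), ergosterol and fatty acid synthesis (−0.45, 24 genes; ERG4 −2.72, ERG10 −1.68, OLE1 1.46, ERG5 0.96), the unfolded protein response (−0.44, 24 genes; PDI1 −1.80, HAC1 −1.16, SIL1 1.04, DER1 0.19) and stress, trehalose and glycogen (−0.36, 29 genes; GRE3 −2.30, HSP12 −1.85, GDB1 1.37, GAC1 1.25) stood below. Ergosterol synthesis no longer did with scaling (−0.26), quantile normalization (−0.23) or sector centring (−0.16), nor the unfolded protein response with sector centring (−0.31).

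Hexose transport stood above, with a median of 0.62 (15 of 19 genes above 0). HXT2, a glucose transporter, was 2.27 higher on Y10 and MIG2, a glucose-regulated repressor, 1.15 (2 spots), against −0.90 for HXT17 and −0.76 for HXT15. Mitochondrial ribosomal proteins (−0.01, 64 genes; RSM23 0.97, MRPL24 0.49, MRPS35 −1.96, MNP1 −1.82), cytosolic chaperones (−0.02, 25 genes), gluconeogenesis, glyoxylate cycle and glycerol use (0.17, 18 genes), histones (−0.02, 10 genes; HTA1 0.53, HTB1 0.44, HHT2 −0.73, HHF2 −0.41), cell wall and secreted proteins (−0.21, 24 genes; UTR2 0.71, YPS3 0.50, BGL2 −1.87, GAS3 −1.82) and mRNAs with reported upstream open reading frames (−0.39, 9 genes; CBS1 1.35, GCN4 0.70, LEU4 −1.55, SCO1 −0.54, CPA1 −0.46) did not stand apart. Within the chaperone and heat shock list, HSP30 (2.31) and BTN2 (2.18) were higher and SSB2 (−1.86) and HSP12 lower. FBP1 was 1.01 and MDH2 1.09 higher, ACS1 0.80 and GUT1 0.21, whereas GUT2 differed by −0.75, ALD4 by −0.41 and ADH2 by −1.06. ACT1 differed by −1.88.

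Of 4427 genes, 288 were at least 1 log2 unit higher and 537 at least 1 lower on Y10 than on G0, and after quantile normalization 394 and 447. By deposited row number the ribosomal protein median was 0.023 and the hexose transport, unfolded protein response and stress lists no longer stood apart. Under that numbering Y10 was unrelated to G0 across spots (r = 0.037), so these changes do not weigh against the renumbered values. Among genes with 2 or more spots the ribosomal protein median was 0.065 over only 6 genes, RPL41A included, and against lists matched on G0 translation factors, aminoacyl-tRNA synthetases, the tricarboxylic acid cycle, stress, amino acid biosynthesis, the proteasome and ergosterol synthesis no longer stood apart, whereas chaperones (percentile 99.94), ribosome biogenesis (98.9) and cell wall proteins (97.7) did so on the high side. Against lists of the genes nearest in G0 value, chosen after seeing the data, glycolysis (percentile 6.47), the respiratory chain (8.06) and sulfur amino acid metabolism (4.74) no longer stood apart either, and histones (0.58) did so on the low side.

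On both later arrays, 86 genes were at least 1 log2 unit higher and 292 at least 1 lower than on G0, of 4425 genes on all 3 arrays. The numbers were 131 and 225 after quantile normalization and 56 and 276 with sector centring. Genes highest on both included BOR1 (2.96 on Y5, 3.08 on Y10), GLE1 (3.46, 2.43), TYE7, an activator of glycolytic genes (3.53, 2.35), TIM22, of mitochondrial protein import (2.30, 2.38), GDA1 (2.17, 2.26), GLN1 (2.20, 2.14), YCX1 (2.85, 1.98), HSP30, QCR6 and UTP6. Genes lowest on both included PUS9 (−6.38, −5.31), TAL1, transaldolase (−4.11, −4.25), COQ1 (−3.92, −4.09), VMA4, of the vacuolar ATPase (−3.44, −3.31), RPL1A, COQ5 (−2.83, −2.79), RPL7A, PDC5, GLK1 and CPR1, a cyclophilin (−2.54, −2.57). Independent lists of these sizes would share 11.8 higher and 53.7 lower genes, and simulated unchanged arrays sharing G0 gave 37.8 and 36.5. The simulation held only the error between repeat spots. A spread between hybridisations, which it left out, could raise its numbers. The differences from G0 correlated with r = 0.701 across genes against 0.560 in that simulation, and their covariance was 0.423 against 0.167, a difference of 0.255. The same sign was found for 73.9% of genes against 68.8% simulated. G0 is 1 array and cannot be split, so part of the excess may come from sharing it. The same limit holds for single genes. On G0, Y5 and Y10, PUS9 lay at 5.30, −1.085 and −0.007 and COQ1 at 4.13, 0.21 and 0.04. BOR1 lay at −3.23, −0.27 and −0.145 and GDA1 at −2.19, −0.03 and 0.06. Each had 1 spot, and its extreme G0 value alone can make both differences large. TAL1 (−2.02 on Y5, −2.17 on Y10) and GLN1 (1.96, 1.90), by contrast, also lay far from the median on both later arrays.

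**Figure D2:**
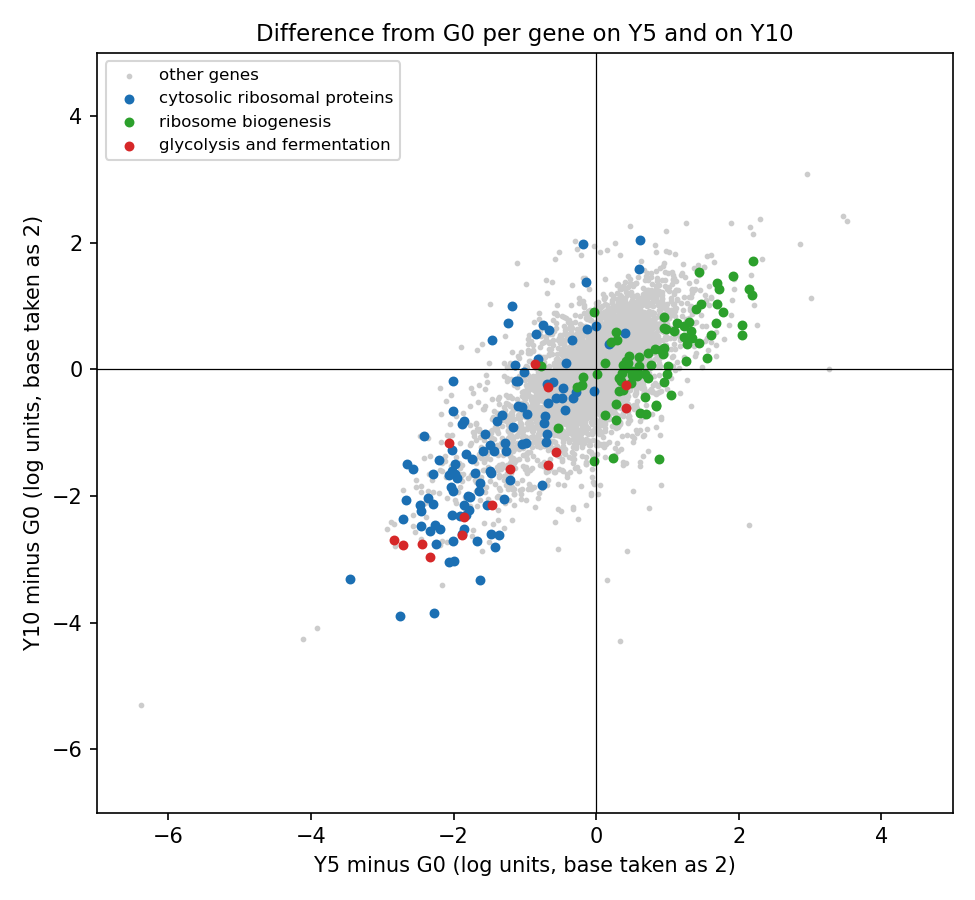
Difference from G0 of each of 4425 genes on Y5 (x axis) and Y10 (y axis), in log2 units, 1 point per gene, with 3 gene lists coloured. Most ribosomal protein and glycolytic genes lie below 0 on both axes (medians over the plotted genes −1.49 and −1.29, and −1.46 and −1.57), and ribosome biogenesis genes lie higher on the Y5 axis (median 0.77) than on the Y10 axis (0.14).

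Between Y5 and Y10, ribosome biogenesis mRNAs were lower on Y10, with a median of −0.60 and 73 of 81 genes below 0. Aminoacyl-tRNA synthetases (−0.71, 19 genes), the tricarboxylic acid cycle (−0.63, 11 genes), cell wall and secreted proteins (−0.57, 25 genes), glycolysis and fermentation (−0.48, 15 genes), translation factors (−0.45, 29 genes), amino acid biosynthesis (−0.42, 53 genes) and sulfur amino acid metabolism (−0.39, 21 genes) were lower too. Higher on Y10 were stress, trehalose and glycogen (0.50, 25 of 30 genes above 0), hexose transport (0.45, 19 genes), cytosolic chaperones (0.42, 25 genes), mitochondrial ribosomal proteins (0.24, 64 genes) and, by little, cytosolic ribosomal proteins (0.19, 108 genes), which turned to −0.31 when the arrays were scaled to one spread. Among genes with 2 or more spots cytosolic ribosomal proteins (0.23, 6 genes) no longer stood apart, and the mitochondrial ones had a median of 0.78 (5 genes). The respiratory chain (0.22, 30 genes), gluconeogenesis (0.13, 18 genes), the unfolded protein response (0.07, 24 genes), the proteasome (−0.06, 32 genes), histones (−0.06, 10 genes), ergosterol synthesis (−0.14, 24 genes) and mRNAs with upstream open reading frames (−0.15, 9 genes; GCN4 −1.55) did not stand apart. Gluconeogenesis did with sector centring (0.31), and the respiratory chain over genes on all 3 arrays (0.22) or without the outer 0.5% (0.23). All lists that stood lower on Y10 had Y5 medians above 0, such as ribosome biogenesis (0.83) and synthetases (1.13). Those that stood higher had Y5 medians below 0, such as stress genes (−0.525), except chaperones (0.35). Lists were not matched on the Y5 value, so a return of high or low Y5 values toward the median was not tested.

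Among genes measured on all 3 arrays and by the mean over spots, the largest single differences between Y5 and Y10 were PET122 (2.78), a translational activator of mitochondria, KRE2 (2.54), a mannosyltransferase, NNT1 (2.38), HOR7 (2.34) and DAD1 (2.32) on the high side, and NVJ3 (−4.63), UGA4 (−4.60), the permease for gamma-aminobutyrate, PRM6 (−3.48), RXT2 (−3.30) and BSC1 (−3.26) on the low side. DDR2, which had no value on G0 and was named after its value was seen, differed by 5.21 for Y10 minus Y5. For PET122, which had 2 discordant spots on Y5 and 1 on Y10, the spot measured on both differed by only 0.76. The other genes ranked here had 1 spot on each array. NVJ3 (−4.87), PRM6 (−3.58) and RXT2 (−2.69) were extreme on Y10 only, and BSC1 (3.22) on Y5 only. Over 453 genes with 2 spots, the Y10 minus Y5 differences of the 2 spots correlated with only r = 0.197. Of 4435 genes on Y5 and Y10, 167 were at least 1 log2 unit higher and 235 at least 1 lower on Y10, against 194 and 205 after quantile normalization and 127 and 146 with sector centring. The tricarboxylic acid cycle list no longer stood apart with sector centring (−0.18) or with the last 60 spots added (−0.20), and sulfur amino acid metabolism no longer did with sector centring (−0.17), scaling to one spread (−0.22) or quantile normalization (−0.18). By deposited row number, chaperones turned to −0.19 and the lists of translation factors, glycolysis, the tricarboxylic acid cycle, hexose transport and sulfur amino acid metabolism no longer stood apart. Under that numbering Y10 was unrelated to Y5 across spots (r = 0.016), so these changes do not weigh against the renumbered values.

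Longer coding sequences, which can hold more ribosomes, had higher values on all 3 arrays. Spearman's rho across genes between the value and coding length was 0.317 on G0, 0.478 on Y5 and 0.344 on Y10, where genes are not independent replicates. Genes under 500 nt had medians of −0.45, −0.53 and −0.20, and genes of 2000 nt or more 0.28, 0.29 and 0.20. For the differences rho was 0.124 for Y5 minus G0, −0.0391 for Y10 minus G0 and −0.223 for Y10 minus Y5. With scaling to one spread these were 0.175, 0.0690 and −0.0999, and after quantile normalization the last 2 were 0.0272 and −0.144.

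**Figure D3:**
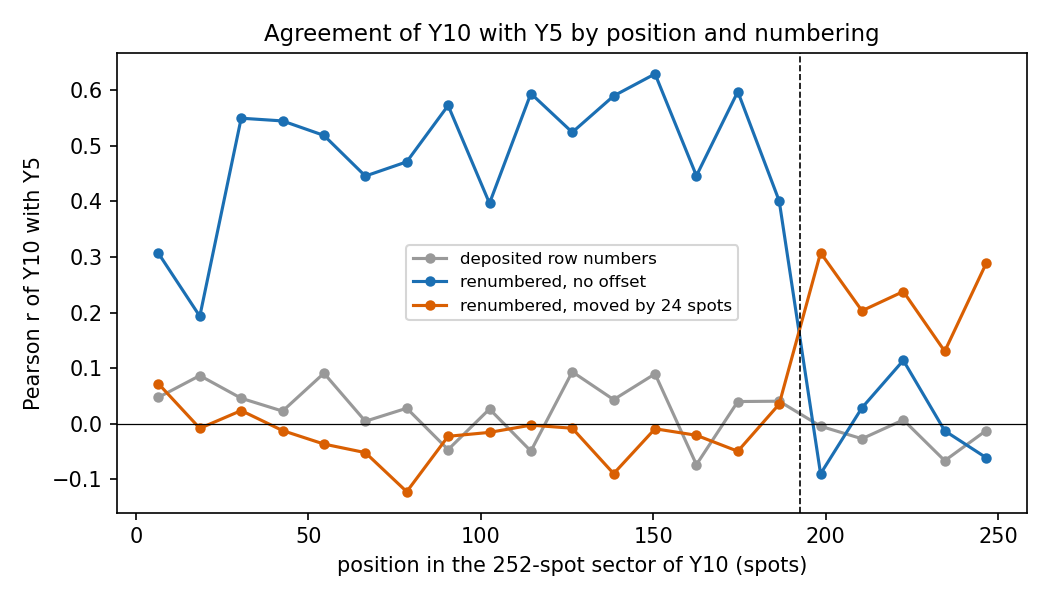
Pearson correlation across spots between Y10 and Y5 (y axis) by position in the 252-spot sectors of Y10 (x axis), 1 point per row of 12 spots, with the dashed line after spot 192. Renumbered without an offset, the first 16 rows lie between 0.193 and 0.629, and by deposited row number between −0.0737 and 0.0934.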

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

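The tests of the Y10 numbering and the choice of these genes were made after the results were seen. Of 4425 genes on all 3 arrays, 1 was at least 1 log2 unit higher than G0 on Y5 and at least 1 lower on Y10, and 3 were the other way round. UGA4 differed from G0 by 2.15 on Y5 and by −2.45 on Y10. PET122 stood at −1.11 and 1.68, KRE2 at −1.50 and 1.04, and RPL36A, whose spots near-identical RPL36B can share and which was named after its value was seen, at −1.18 and 1.0. With 1 array per group these opposite differences were not tested, and PET122 rests on 2 discordant spots on G0 and Y5 (Y5 minus G0 of −2.54 and 0.33), of which the 1 measured on Y10 differed from G0 by 1.09 there. Without the outer 0.5% of values PET122 stood at 0.92 on Y5.

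Spots without a gene name were used in no comparison. Of 2049 such spots with a value on G0 and Y5, 127 (6.20%) lay at least 1 log2 unit from the median with the same sign on both arrays, against 270 of 6583 named spots (4.10%). Their values were also more spread (SD 1.09 on G0 and 1.04 on Y5, against 0.711 and 0.690) and less correlated between G0 and Y5 (r = 0.333 against 0.429), so the higher share does not show more signal. The 1814 values in the last 60 spots of each Y10 sector were not used either, and they correlated with Y5 with r = 0.201 when moved by 24 spots.

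By deposited row number, the Y10 array was unrelated to G0 and Y5. A candidate explanation is that Y10 was numbered on a print with fewer spots per sector (252, not 276). Within Y10 alone, the repeat spots of a gene correlated at r = 0.309 after renumbering, against at most 0.151 under 83 other numberings. This argues against an array of noise only, since the lower 95% bound of that correlation was 0.223. A biological difference of the Y10 sample alone is argued against by the deposited numbering itself, under which repeat spots correlated at r = 0.0337 (upper bound 0.107), and what the last 60 spots of each sector hold stays open.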

How the results depend on the processing

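Reading Y10 by deposited row number, adding its last 60 spots, centring each sector, keeping only genes with 2 or more spots and drawing lists from the genes nearest in G0 value were chosen after seeing the data, and the other settings before. All settings fixed before were run, and a list with fewer than 5 genes left under a setting has no value. Of 426 values of list medians that stood apart, 7 changed sign and 13 others left the interval of the median, and of 212 values of the other lists 23 changed sign and 3 left it. These values include lists without pairs named by a final A or B, which averaging such pairs could not change. Among medians with a percentile there were 518 values over 10 settings. Some belong to medians that did not stand apart to begin with and so could not lose a call. Of the 518, 35 no longer stood apart, 17 came to stand apart and 1 moved to the other side. They include Y10 by deposited row number, under which Y10 was unrelated to the other arrays. Against lists matched on the G0 value 14 calls were lost and 5 gained, and against lists of the nearest genes 17 and 6. Of the named-gene differences, 2481 moved by less than their error, 71 moved more and 4 reversed. Of the counts, 60 stayed within 1.5 times and 32 did not. Of the coding-length correlations, 50 stayed, 8 moved and 2 reversed. With no intensities, what signal over background limits is not known. No paired analysis was possible because each group has 1 array and the result comes from no test. The cause of each change below was not tested, although counts over fewer genes are smaller by construction.

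Scaling to one median absolute deviation gave coding-length rho of 0.175 for Y5 minus G0, 0.0690 for Y10 minus G0, which reversed, and −0.0999 for Y10 minus Y5. The same scaling gave medians of −1.73 for ribosomal proteins and −0.34 for aminoacyl-tRNA synthetases in Y10 minus G0, and −0.31 for ribosomal proteins in Y10 minus Y5, which reversed. Quantile normalization gave 346 genes lower on Y5 than on G0 and 131 higher on both later arrays, a synthetase median of −0.37 for Y10 minus G0, and coding-length rho of 0.0272 for Y10 minus G0, which reversed, and −0.144 for Y10 minus Y5. Without the outer 0.5% of values, PET122 reversed to 0.92 and QCR10 to −0.17 for Y5 minus G0, and QCR10 to 0.56 for Y10 minus Y5, each by losing 1 of its spots.

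Under the deposited row numbers Y10 was unrelated to G0 and Y5, so the values of this setting do not weigh against the renumbered ones. With Y10 by deposited row number, 435 genes were higher on Y10 than on G0, 574 higher and 617 lower than on Y5, and 54 higher than on G0 on both later arrays. Coding-length rho was 0.00285 on Y10, −0.239 for Y10 minus G0 and −0.354 for Y10 minus Y5. For Y10 minus G0 the ribosomal protein median reversed to 0.023 and the synthetase median was −1.17. For Y10 minus Y5 the medians were 1.56 for ribosomal proteins, 0.50 for mitochondrial ribosomal proteins, −0.74 for ribosome biogenesis, −0.083 for translation factors, −1.21 for synthetases and −0.19 for chaperones, the last reversed. With the last 60 spots of each sector added, TEF1 reversed to 1.14 for Y10 minus Y5. With each sector centred, 146 genes were lower on Y10 than on Y5, 56 were higher on both than on G0, and rho on Y10 was 0.377.

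Among genes with 2 or more spots, a smaller set by construction, 26 were higher and 46 lower on Y5 than on G0, 17 higher and 21 lower on Y10 than on G0, 8 higher and 18 lower on Y10 than on Y5, and 4 higher and 11 lower on both than on G0. Coding-length rho for Y10 minus G0 was −0.136. The Y5 minus G0 medians were −0.69 for ribosomal proteins, −0.11 for mitochondrial ribosomal proteins and −0.27 for stress genes, and reversed to 0.34 for translation factors, 0.22 for amino acid biosynthesis and 0.40 for ergosterol synthesis. The ribosomal protein median reversed to 0.065 for Y10 minus G0, over 6 genes, and that of mitochondrial ribosomal proteins was 0.78 for Y10 minus Y5, over 5.

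At 1.5-fold, 793 genes were higher and 1155 lower on Y5 than on G0, 789 and 1042 on Y10 than on G0, 572 and 655 on Y10 than on Y5, and 361 and 582 on both than on G0. At 3-fold these were 50 and 231, 45 and 213, 36 and 50, and 12 and 106.

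Against random lists matched on the G0 value, these lists were no longer outside the central 95% for Y5 minus G0, with percentiles of 23.6 for translation factors, 13.6 for the tricarboxylic acid cycle, 4.995 for chaperones, 65.7 for amino acid biosynthesis, 57.2 for sulfur amino acid metabolism, 14.5 for the proteasome and 9.74 for ergosterol synthesis. For Y10 minus G0 they were 9.54 for translation factors, 74.3 for synthetases, 6.39 for the tricarboxylic acid cycle, 35.1 for stress genes, 6.21 for amino acid biosynthesis, 9.09 for the proteasome and 54.6 for ergosterol synthesis. Lists that came to stand apart were synthetases (99.95) and cell wall proteins (100) for Y5 minus G0, and ribosome biogenesis (98.9), chaperones (99.94) and cell wall proteins (97.7) for Y10 minus G0.

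Against lists drawn from the genes nearest in G0 value, calls were lost for Y5 minus G0 by translation factors (34.6), the tricarboxylic acid cycle (8.53), chaperones (9.17), amino acid biosynthesis (63.7), sulfur amino acid metabolism (87.6), the proteasome (15.5) and ergosterol synthesis (7.34). For Y10 minus G0 calls were lost by translation factors (20.85), synthetases (93.5), glycolysis (6.47), the tricarboxylic acid cycle (6.265), the respiratory chain (8.06), stress genes (25.4), amino acid biosynthesis (11.6), sulfur amino acid metabolism (4.74), the proteasome (6.455) and ergosterol synthesis (64.0). Calls were gained by synthetases (99.98) and cell wall proteins (100) for Y5 minus G0, and by ribosome biogenesis (98.65), chaperones (99.95), cell wall proteins (99.9) and, on the low side, histones (0.58) for Y10 minus G0.

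Some list medians kept their direction but no longer stood apart. For Y5 minus G0 these were translation factors (−0.09) and ergosterol synthesis (−0.02) after quantile normalization, and translation factors (−0.25), sulfur amino acid metabolism (−0.34) and ergosterol synthesis (−0.12) over genes on all 3 arrays. Among genes with 2 or more spots they were mitochondrial ribosomal proteins (−0.11) and stress genes (−0.27). For Y10 minus G0 they were synthetases and ergosterol synthesis (−0.26) with scaling to one spread, synthetases and ergosterol synthesis (−0.23) after quantile normalization, the unfolded protein response (−0.31) and ergosterol synthesis (−0.16) with sector centring, and stress genes (−0.17) and ergosterol synthesis (−0.14) among genes with 2 or more spots. For Y10 minus Y5 they were sulfur amino acid metabolism with scaling to one spread (−0.22), quantile normalization (−0.18) or sector centring (−0.17), the tricarboxylic acid cycle with sector centring (−0.18) or the last 60 spots added (−0.20), and ribosomal proteins (0.23) among genes with 2 or more spots. With deposited row numbers, the same held for hexose transport (0.30), the unfolded protein response (−0.14) and stress genes (−0.28) in Y10 minus G0, and for glycolysis (−0.31), the tricarboxylic acid cycle (−0.24), hexose transport (0.11), sulfur amino acid metabolism (−0.30) and translation factors in Y10 minus Y5.

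Lists that came to stand apart were cell wall proteins for Y5 minus G0 with scaling (0.34), quantile normalization (0.36) or sector centring (0.34), and ribosome biogenesis for Y10 minus G0 with scaling (0.28), quantile normalization (0.31), sector centring (0.22) or the last 60 spots (0.16). The respiratory chain did so for Y10 minus Y5 over genes on all 3 arrays (0.22) or without the outer 0.5% (0.23). Sector centring brought out upstream open reading frames for Y5 minus G0 (0.33), cell wall proteins for Y10 minus G0 (−0.32) and gluconeogenesis for Y10 minus Y5 (0.31). Deposited row numbers brought out mitochondrial ribosomal proteins (0.25), chaperones (−0.63) and cell wall proteins (−0.69) for Y10 minus G0 and the unfolded protein response (0.41) for Y10 minus Y5, and genes with 2 or more spots mitochondrial ribosomal proteins (0.78) for Y10 minus G0.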

Other observations

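The tests on the G0 value, on slide position and on abundant transcripts were framed after the results they bear on were seen, and the test on coding length before. Ribosomal protein and ribosome biogenesis mRNAs, both needed to make ribosomes, stood apart on Y5 in opposite directions, with medians of −1.57 and 0.83 on that array. On Y10 they stood at −1.34 and 0.17. With the arrays scaled to one spread, the biogenesis median for Y10 minus G0 was 0.28, against 0.75 for Y5 minus G0. Against lists drawn from the genes nearest in G0 value, chaperones on Y10 (percentile 99.95) and aminoacyl-tRNA synthetases on Y5 (percentile 99.98) were high although their plain differences from G0 were −0.02 and −0.01.

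The lower values of cytosolic ribosomal proteins on Y5 than on G0 could come from short coding sequences, from an effect of abundant transcripts on the dye ratio or from the place of their spots. Random lists matched on the length in the gene table had a median of −0.09, and the ribosomal protein list lay −1.41 from them and below all of them. That length had a median of 771 nt for ribosomal proteins and may include introns. The match may then not hold for their coding sequences. Genes under 500 nt other than ribosomal proteins had a Y5 minus G0 median of −0.03 (523 genes). This argues against short coding sequences as the whole cause. After each sector was centred on its own median, the list median was −1.51. Sector medians ran only from −0.341 to 0.3435 on G0 and from −0.405 to 0.317 on Y5. Differences between sectors were thus too small to give the list median, and place within a sector was not tested. The glycolytic median, for mRNAs also known as abundant, lay −0.12 from the ribosomal protein median for Y5 minus G0, so an effect of abundance stays open. A difference between the G0 and Y5 samples and a difference between 2 single hybridisations both stay open, and the carbon source itself was not tested.

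Most lists that were high on G0 were lower on Y5, which might come from extreme values on 1 array returning toward the median on another. Against lists drawn from the genes nearest in G0 value, glycolysis and fermentation lay at percentile 1.39 (median −1.62 against −1.06), and over 5 draws each the percentile ran from 1.8 to 2.52 with 10 nearest genes per member, 1.21 to 1.58 with 20 and 0.59 to 1.04 with 40. As 1 of these draws passed percentile 2.5, whether this return accounts for all of its difference cannot be told, although the other draws lay below it. Of the 9 other lists with a G0 median of at least 0.5, 7 lay within the central 95% of such lists, from percentile 7.34 for ergosterol synthesis to 87.6 for sulfur amino acid metabolism, in line with such a return, and the remaining 2, aminoacyl-tRNA synthetases (percentile 99.98) and cell wall proteins (percentile 100), were not lower on Y5 (−0.01 and 0.18), so not every list high on G0 fell. The drawn lists also hold any true loss shared by genes high on G0, so a change of these groups stays open.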
